A study of Mus musculus with 4 samples.

How the data were processed

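Total RNA of 4 samples of cultured testes from 2 dpp (days post partum) mice was analysed, 2 with vehicle and 2 with WIN 18,446 at 1 µM, each for 24 h. Per the labels' protocols, tissue lay on agar in medium with 10% fetal bovine serum at 37 °C and 5% carbon dioxide. About 100 ng of total RNA was amplified to cDNA with NuGEN's Ovation kit, and 3.75 µg of that cDNA was fragmented, biotin-labelled and hybridised.

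The deposited value table holds log2 levels, 1 column per array and 1 line per probe set, already normalized between arrays by the authors. The submitters' processing notes name RMA and GCRMA, which are methods of background correction, normalization and summary, without saying which of them made the table, and give no version. The scale was read from the values, which run up to 16.2 with column medians of 3.72, 3.76, 3.83 and 3.72, so they are log2 levels and not centred per probe set. Differences are given as WIN 18,446 minus vehicle. The dimmest probe sets pile up near 2.1, and the highest of the bacterial control probe sets, which have no target in mouse RNA, read 2.22. A gene at or below 2.22 on both arrays of a group has only a bound there, and its fold is given as "at least", the brighter group's mean against 2.22. Differences between low levels depend on this floor. The number of arrays, 2 per group, limits the precision.

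The table holds 45101 probe sets. The 64 control probe sets of the array were left out of all tests, and of the remaining 45037, those with a mean of at least 5 over the 4 arrays were tested, 20895 in all (46.4%). Gene names come from GEO's annotation of the array: 34945 probe sets have 1 symbol, 932 have several and 9160 are unnamed here, and among those tested the numbers are 18601, 540 and 1754. Of the tested probe sets with 1 symbol, 18566 were found by gene ID in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. No gene is named from a probe set with several symbols. Where a gene has several tested probe sets, it is represented by that of highest mean over the 4 arrays, which gives 10970 genes.

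The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with a two-sided test and Benjamini-Hochberg adjustment over the probe sets tested. A probe set with an adjusted p under 0.05 is called here. The fit has 2 residual and 3.19 prior degrees of freedom. An exact permutation test of a single value cannot go below 0.333 with 2 arrays against 2, so none is given. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes, adjusted over the 25 of 27 lists with at least 5 tested members. The alternatives for lists were camera with an estimated correlation, which has only the 2 residual degrees of freedom, and fry. The lists cover the retinoic acid response, retinoid metabolism, germ cell stages, the somatic cells of the testis, cells that can come with it, stress and growth programmes, and control genes. Some genes stand on 2 lists, such as Stra6, Dhrs3, Sall4, Atf3, Btg2 and Aldh1a7.

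The groups, tests, level filter, lists, named genes and all alternatives but 1 were fixed before the data were examined. The genes named are 13 retinoid and germ cell genes always given, the 15 genes per direction with the largest log2 difference among those called whose groups do not overlap, and up to 4 members of each list by smallest p, or up to 6 where more were called. Symbols of clones and predicted genes were passed over. Amh, Hsd17b1, the second probe sets and the genes of the closing section that this rule does not give were chosen after their values were seen. The alternatives were no level filter, a mean of at least 7, quantile normalization again, equal array medians, no variance trend, robust moderation, the replicate number as a block, each array left out in turn, 1 probe set per gene, the mean over a gene's probe sets for lists, and an adjusted p under 0.10. The filter that asks for 2 of the 4 arrays at 5 or above was added after Stra8 was seen to fall under the planned one. When an array is left out, the remaining array of its group is assumed to vary like the other group.

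The fit was tested on simulated data with the real mean levels of the 20895 probe sets. The noise was normal, with the variance that eBayes gave each probe set in the real fit, not its observed spread. Each of 20 runs held 200 changed probe sets, split evenly over the sizes given next. The fit recovered 24.6% of changes of 0.5 log2 units, 70.7% of changes of 1, 97.7% of changes of 2 and 99.9% of changes of 4. False calls were 9.43% of all calls, above the nominal rate, and with none changed there were at most 2 calls in a run. Camera called a list of 20 genes shifted by 0.5 log2 units in 20 of 20 runs and an unshifted list in 0 of 20. Genes varied independently in these runs, which therefore do not test camera on lists of correlated genes. In the real data limma gave 4598 probe sets an unadjusted p under 0.05, so the rates found with 200 changed need not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Scanner files and probe sequences were not used here.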

Results

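Testes taken from 129 strain mice at 2 days post partum were kept in organ culture for 24 h, with either WIN 18,446 at 1 µM or its vehicle, dimethyl sulfoxide. Transcript levels were then measured on Affymetrix Mouse Genome 430 2.0 microarrays. The compound is a known inhibitor of the retinaldehyde dehydrogenases, the enzymes that make retinoic acid from retinaldehyde. Retinoic acid is the vitamin A derivative that starts spermatogonial differentiation and meiosis. The series held 4 arrays, 2 for each group. The labels number the samples but do not say whether they came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value. Median log2 levels were 3.72 and 3.76 on the vehicle arrays and 3.83 and 3.72 on the treated arrays, and between 46.4% and 46.6% of all probe sets reached a level of 5. Across the 20895 probe sets tested, which are not independent replicates, Pearson's r was 0.992 between the vehicle arrays, 0.985 between the treated arrays and 0.964 to 0.976 between arrays of different groups. The difference between the 3' and 5' control probe sets of Gapdh, a sign of RNA quality, was 0.83 and 0.76 log2 units on the vehicle arrays and 0.83 and 0.72 on the treated arrays. Treated array 1 stood apart in other control probe sets: the 5' probe set of 18S ribosomal RNA read 6.55 there against 8.12, 8.17 and 8.67 on the other arrays, its middle probe set 13.79 against 14.17 to 14.62, and that of the B1 repeat 13.52 against 12.73 to 12.93.

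The comparison asks which transcripts of the neonatal testis differ after a day with the inhibitor. Stra8, the gene that retinoic acid induces in germ cells before meiosis, was near background on both treated arrays, while Cidea, a lipid droplet protein, Mybphl, a myosin-binding protein, and S100a8, a myeloid calcium-binding protein, were among the genes that fell most. Spata21, a spermatogenesis-associated gene, and Kcnh1, a potassium channel, rose most, and 20 of 32 tested cell cycle genes rose. Of the 20895 probe sets tested, limma called 1083 (5.18%), of which 475 were higher and 608 lower with WIN 18,446. With each gene represented by its probe set of highest mean, 322 of 10970 genes rose and 380 fell. At least a 2-fold difference was seen in 228 of the higher and 341 of the lower probe sets called, and at least a 4-fold difference in 60 and 131. The 2 groups did not overlap in 53.1% of the probe sets tested, against 33.3% by chance for 2 arrays against 2. The count rests on both vehicle arrays and on the settings of the test: limma called 0 probe sets without vehicle array 1 (2455 at an unadjusted p under 0.05), 0 without vehicle array 2 (2820), 664 without treated array 1, 1398 without treated array 2 (480 higher and 918 lower), 372 without a variance trend and 3 without the level filter.

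Genes of the retinoic acid response were lower in the treated samples. Stra8 stood at 6.72 ± 0.42 (log2, SD, n = 2) with vehicle and at 2.04 ± 0.0024 with WIN 18,446, where both arrays lay below the highest bacterial control probe set (2.22), so that it was at least 22.7-fold lower. Its mean over the 4 arrays lay under the planned level filter of 5. Under a filter chosen after seeing this, which asks for 2 arrays at 5 or above, limma gave Stra8 an adjusted p of 0.00718, and with no filter 0.075. Stra6, the cell surface receptor for retinol uptake, fell from 8.23 ± 0.06 to 6.39 ± 0.19 (log2 difference -1.84, SE 0.20, adjusted p = 0.0192). Dhrs3, a retinaldehyde reductase that retinoic acid induces, fell by 1.36 on the log2 scale (SE 0.12, adjusted p = 0.0135). Rarres1 (-0.68, adjusted p = 0.0288) and the transcription factor Gata6 (-0.84, adjusted p = 0.0311) also fell. Of 12 tested members of the retinoic acid response list, 4 fell, 0 rose and 8 were not called; adjusted over the list alone, 5 fell and 1 rose. The list as a whole was lower in camera (adjusted p = 0.00436) and in limma's fry test (adjusted p = 0.0322). The camera call was lost with an estimated correlation (p = 0.0764, adjusted p = 0.586 with an estimated correlation). The estimate for this list was -0.05, under the preset 0.01, so correlation between its members does not account for the loss. That form of camera has only 2 residual degrees of freedom. Its adjusted p of 0.586 was also that of the housekeeping list, and so is not particular to this list. Btg2, an antiproliferative gene on this list, was 1.67 log2 units higher and was not called (adjusted p = 0.0592).

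Among the genes of retinoid synthesis, storage and breakdown, Aldh1a7, a close relative of Aldh1a1, rose from 9.86 ± 0.11 to 10.87 ± 0.06 (log2 difference 1.01, SE 0.12, adjusted p = 0.0224). Aldh1a1, which encodes a retinaldehyde dehydrogenase, was at 14.42 ± 0.09 with vehicle and 14.76 ± 0.10 with WIN 18,446 (adjusted p = 0.0711). The log2 difference was -1.06 for Aldh1a2 (adjusted p = 0.0724) and -0.24 for Cyp26b1, the enzyme that degrades retinoic acid in the fetal testis (adjusted p = 0.479). For Rdh10, which oxidises retinol, the probe set of higher mean differed by -1.02 (adjusted p = 0.0889), and the other fell by 1.14 (adjusted p = 0.0364). Aldh1a3, Rarb, Cyp26a1, Crabp2, Lrat, Rec8 and Kit had mean levels under 5 in all their probe sets, from 2.06 for Rarb to 2.92 for Kit, and were not tested. Of 19 tested members of this list 1 rose, 2 fell (Stra6 and Dhrs3) and 16 were not called; adjusted over the list alone, 3 rose and 4 fell. Camera did not call the list (adjusted p = 0.751).

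**Figure D1:**
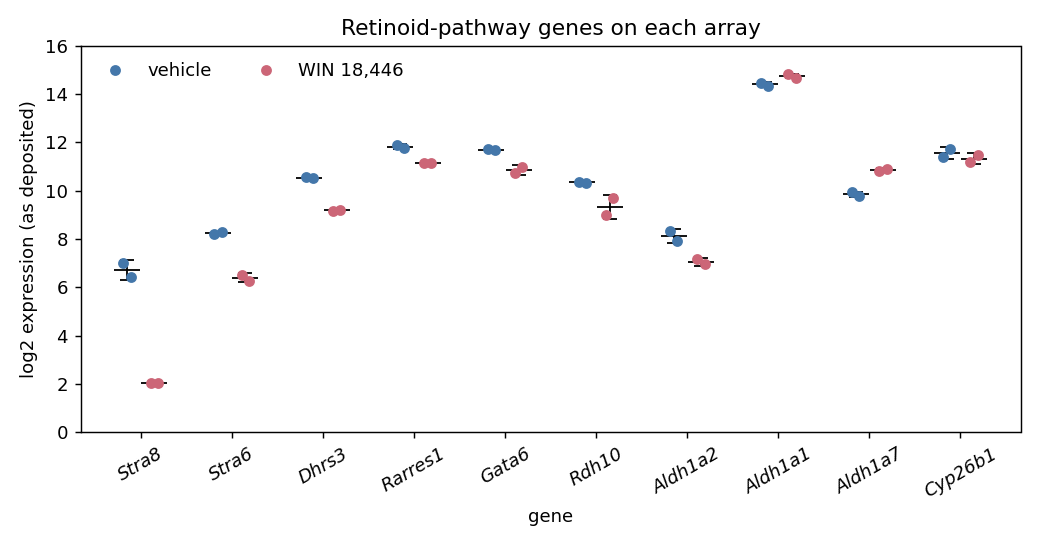
The plot shows the deposited log2 level of 10 genes of retinoid metabolism and response on each of the 4 arrays, with vehicle in blue and WIN 18,446 in red; black bars give the group mean and its SD over 2 arrays. Stra8 lies at 2.04 on average with WIN 18,446 and at 6.72 with vehicle, and Stra6 and Dhrs3 are lower on both treated arrays.

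Germ cell genes as a group were not called. Sall4, a transcription factor of undifferentiated germ cells, fell from 13.53 ± 0.03 to 12.93 ± 0.0005 (log2 difference -0.60, adjusted p = 0.0157), and the piRNA pathway helicase Tdrd9 fell by 1.02 on the log2 scale (adjusted p = 0.0301). Of 27 tested germ cell genes 2 fell, 0 rose and 25 were not called; adjusted over the list alone, 3 fell and 2 rose (camera adjusted p = 0.948). Of 17 genes of meiotic entry and prophase 0 were called, with Syce2 at a log2 difference of 0.65 (adjusted p = 0.0527) and Tex12 at -0.64 (adjusted p = 0.0603); adjusted over the list alone, 1 rose and 1 fell (camera adjusted p = 0.975). None of 16 undifferentiated spermatogonia genes was called in either way of adjusting (camera adjusted p = 0.809). Among 10 genes of differentiating spermatogonia, the cyclin Ccnd2 rose by 0.52 log2 units (adjusted p = 0.0389), Sall4 fell and 8 were not called; adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.222). For the meiotic and the undifferentiated spermatogonia lists the median was positive (0.10 and 0.12) and the mean negative (-0.02 and -0.03).

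Cldn11, Sox9 and 4 more Sertoli cell genes fell. Cldn11, the claudin of the tight junctions between Sertoli cells, fell from 12.70 ± 0.06 to 11.45 ± 0.0007 (log2 difference -1.25, SE 0.08, adjusted p = 0.00781). Sox9, a transcription factor of Sertoli cells, fell by 1.15 on the log2 scale (SE 0.10, adjusted p = 0.0121). Sox8 (-0.82), Wt1 (-0.58), the hedgehog ligand Dhh (-0.43) and Cst9 (-0.27) also fell, with adjusted p-values from 0.0268 to 0.048. Amh was 1.25 and Hsd17b1 2.09 log2 units higher, and neither was called (adjusted p = 0.0575 and 0.0519). Without vehicle array 1 the Hsd17b1 difference was 1.48, and without vehicle array 2 it was 2.70. Of 27 tested Sertoli genes 6 fell, 0 rose and 21 were not called; adjusted over the list alone, 11 fell and 4 rose. Camera did not call the list (adjusted p = 0.174), while fry, which asks whether the genes move one way on balance, gave an adjusted p of 0.0184.

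Nr0b1, an orphan nuclear receptor of steroidogenic and Sertoli cells, fell 12.9-fold, from 11.65 ± 0.04 to 7.95 ± 0.18 (log2 difference -3.69, SE 0.15, adjusted p = 0.00387), and was the only 1 of 13 tested genes of the Leydig cell and steroidogenesis list to be called (1 adjusted over the list alone; camera adjusted p = 0.159). Desmin (Des, -1.47) and osteoglycin (Ogn, -0.66) fell among 20 peritubular and stromal genes (adjusted p = 0.0349 and 0.0419; 2 adjusted over the list alone; camera adjusted p = 0.0652). The endothelial list was lower, with a median log2 difference of -1.01 over 13 genes (camera adjusted p = 0.000595). That call was lost when the correlation was estimated (adjusted p = 0.586 with an estimated correlation). The vehicle arrays also differed, with list means of 8.42 and 8.96, against 7.89 and 7.72 on the treated arrays. Robo4, a receptor of blood vessel cells, fell (-1.01, adjusted p = 0.0435), 12 were not called, and adjusted over the list alone 7 fell. None of 7 macrophage genes was called, over all genes or adjusted over the list alone (camera adjusted p = 0.418). Too few members of the erythroid (2) and the epididymal, mesonephric and mesothelial (4) lists were tested for a list test: Hbb-b2, a beta-globin, was 1.42 log2 units lower and was not called (adjusted p = 0.0618), and Krt18 differed by -0.01, a sign that flipped when array medians were set equal (0.00046) or values were quantile normalized again (0.05). Adjusted over the list alone, 1 erythroid gene fell and 0 epithelial genes were called.

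Cell cycle genes rose together. Cenpf, a kinetochore protein, rose from 9.61 ± 0.24 to 10.97 ± 0.02 (log2 difference 1.36, SE 0.15, adjusted p = 0.0195), Kif23, a kinesin of cytokinesis, rose by 0.98 (adjusted p = 0.0199), and the replication helicase subunit Mcm6 by 0.57 (adjusted p = 0.0192). The transcription factor E2f1 (1.14) and the mitotic activator Cdc20 (0.76) rose too (adjusted p = 0.0242 and 0.0208). Of 32 tested members 20 rose, 0 fell and 12 were not called; adjusted over the list alone, all 32 rose. The median log2 difference was 0.81, and camera gave an adjusted p of 4.54e-23. The estimated correlation between the members was 0.667, and with it the call was lost (adjusted p = 0.586 with an estimated correlation). List means were 11.21 and 11.51 on the vehicle arrays, and 12.14 and 12.26 on the treated arrays. The endothelial list, with its median of -1.01, differed in the same samples.

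Genes of the integrated stress response rose as well. Chac1, a glutathione-degrading enzyme induced by Atf4, rose 8.44-fold, from 6.71 ± 0.18 to 9.79 ± 0.47 (adjusted p = 0.0134), and the mitochondrial folate enzymes Shmt2 and Mthfd2 rose by 1.07 and 0.65 log2 units (adjusted p = 0.0115 and 0.0242). Aldh18a1, an enzyme of proline synthesis, and the amino acid transporter subunit Slc3a2 rose by 0.67 and 0.50. On this list 7 of 25 rose, 0 fell and 18 were not called; adjusted over the list alone, 15 rose (camera adjusted p = 1.23e-09, and adjusted p = 0.586 with an estimated correlation). The hypoxia and glycolysis list was also higher, with 7 of 27 up, 0 down and 20 not called, and 17 up adjusted over the list alone (camera adjusted p = 1.71e-08, and adjusted p = 0.586 with an estimated correlation). Its members included Ldha (0.38), Tpi1 (0.44), Bnip3 (0.57) and Ndrg1 (1.19). List means were 11.846 and 12.141 on the vehicle arrays, and 12.464 and 12.435 on the treated arrays. Among 24 immediate early genes Atf3, Egr2 and Nr4a1 rose by 1.38, 0.86 and 0.71, 21 were not called and 6 rose adjusted over the list alone (camera adjusted p = 0.00436, and adjusted p = 0.586 with an estimated correlation). The immediate early call was lost without treated array 2 (camera adjusted p = 0.0724). The cholesterol synthesis list was lower by a median of 0.15 log2 units over 20 genes, of which Pmvk fell (-0.52, adjusted p = 0.0468) and 19 were not called, with 1 adjusted over the list alone (camera adjusted p = 0.00357, and adjusted p = 0.586 with an estimated correlation).

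The remaining lists were not called by camera. Among 18 aldehyde and alcohol dehydrogenases, Aldh1l2, Aldh1a7 and Aldh18a1 rose (4 up and 3 down adjusted over the list alone; adjusted p = 0.975, with a negative median of -0.09 and a positive mean of 0.04). Among 18 p53 targets Perp rose by 2.06 and Plk2 fell by 0.89 (3 up and 1 down adjusted over the list alone; adjusted p = 0.847, with a median of -0.03 and a mean of 0.13). Fbln2 rose by 2.23 log2 units while Timp2 and Nid2 fell among 29 extracellular matrix genes (1 up and 3 down adjusted over the list alone; adjusted p = 0.482). Gsta2 rose by 0.76 among 17 NRF2 and AHR targets (adjusted p = 0.159), Fkbp4 fell by 0.49 among 20 heat shock genes (adjusted p = 0.0974), and Oasl2 fell by 1.96 among 9 interferon response genes (adjusted p = 0.975, with a median of 0.02 and a mean of -0.20), each being the 1 call adjusted over the list alone. None of 17 FGF, BMP and TGF-beta feedback targets was called (1 up and 1 down adjusted over the list alone; adjusted p = 0.15). None of the 42 ribosomal protein genes (adjusted p = 0.874, median -0.0021, with a test direction opposite to the median) and none of the 12 housekeeping genes (adjusted p = 0.372, median 0.06) was called, and none was adjusted over the list alone. Each gene is represented by its brightest probe set, and another probe set of Rps9 was called lower in limma (-4.41, adjusted p = 0.000389).

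**Figure D2:**
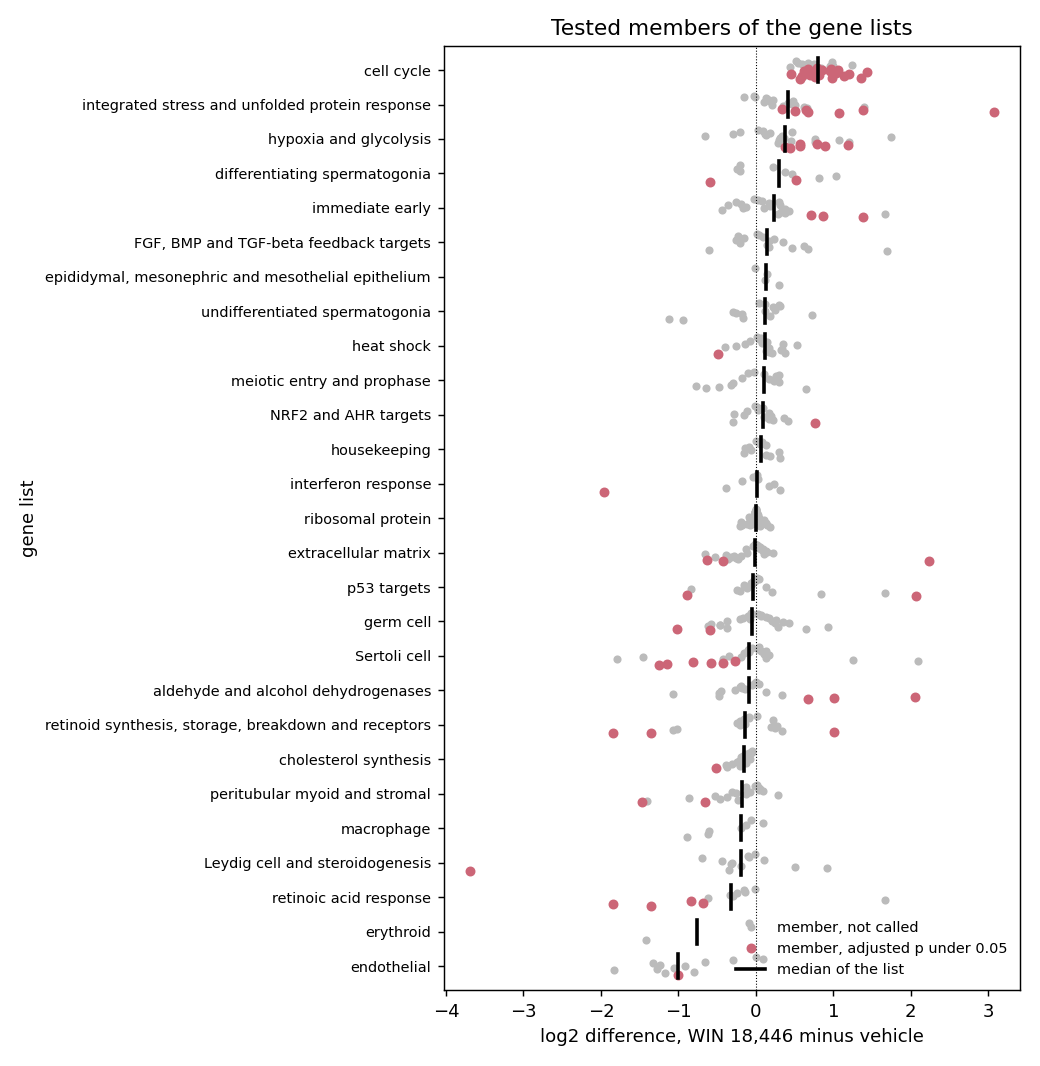
The plot shows the log2 difference (WIN 18,446 minus vehicle, horizontal axis) of each tested member of 27 gene lists; each point is 1 gene, red where limma called it, and the black bar is the list's median. The cell cycle list has the highest median (0.81) and the endothelial list the lowest (-1.01).

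Among single genes, Spata21 rose 81.5-fold, from 2.61 ± 0.0049 to 8.95 ± 0.04 (adjusted p = 0.0029), and Kcnh1 72.2-fold, from 4.51 ± 0.61 to 10.68 ± 0.26 (adjusted p = 0.00561). Miox, the enzyme that breaks down myo-inositol, rose 55.2-fold, from 3.68 ± 1.30 to 9.47 ± 0.54, and Mab21l3 51.4-fold (adjusted p = 0.0195 and 0.00722). Without vehicle array 1 the fold of Miox was 29.2, and without vehicle array 2 it was 104. They were followed by the carbonic anhydrase Car12 (22.7-fold), Rimbp2 (21.2-fold), Minar1 (16.1-fold), Zg16 (10.4-fold) and Pdha2 (9.17-fold), and by Sfrp4, a secreted Wnt inhibitor, Chac1, Tnnc1, Gper1, Sgpp2 and Ctse, at 7.65-fold to 8.7-fold. For Pdha2 (4.13 ± 1.13 with vehicle) the fold was 16 without vehicle array 1 and 5.26 without vehicle array 2. A second probe set of Ctse, a cathepsin, went the other way (-1.84).

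Cidea fell 295-fold, from 11.90 ± 0.05 to 3.69 ± 1.5 (log2 difference -8.20, SE 0.68, adjusted p = 0.0118). Mybphl was at least 118-fold lower, from 9.10 ± 0.80 to a background level of 2.03 ± 0.0035 (adjusted p = 0.00619). S100a8 fell from 12.35 ± 0.02 to 6.29 ± 1.78 and its partner S100a9 from 12.52 ± 0.06 to 7.39 ± 1.79 (adjusted p = 0.0257 and 0.0351), with a wide spread between the treated arrays. Without treated array 1 the folds were 142 for Cidea, 28.0 for S100a8, 14.5 for S100a9 and 13.4 for Plekhb1, and without treated array 2 they were 614, 160, 83.5 and 33.2. Cytip fell 58.0-fold, Myoz2, a sarcomere protein, 48.4-fold, and Fstl3, a binder of activin, 37.6-fold. The vitamin D receptor Vdr fell 28.7-fold, from 11.23 ± 0.21 to 6.39 ± 0.69 (adjusted p = 0.00999), the stefin Stfa2l1 28.5-fold and the claudin Cldn23 27.8-fold. Esyt3, Hhatl, Plekhb1, Prss12 and Cuedc1 fell by 19.9-fold to 26.4-fold, and for Cuedc1 a second probe set was nearly level (-0.11). In each gene said here to have risen or fallen, both treated arrays lay on the same side of both vehicle arrays. The same held for all 1083 called probe sets, so it is no separate check.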

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

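Of the tests in this part, the draw of level-matched lists was set before its result was seen; all the others were chosen after.

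The level filter left 24142 probe sets untested, and in 22 of them both treated arrays lay at least 2 log2 units above both vehicle arrays; 33 lay as far below. The 22 drew attention as a signal in data outside the comparison. The transferrin receptor control probe set at the 3' end, also outside it, averaged 6.32 with vehicle and 7.61 with WIN 18,446, a difference of 1.29 log2 units.

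Of the 3 ways to split the 4 arrays into pairs, 1 (the real split) called as many as 1083 probe sets, and the highest other split called 0 in limma (216 and 179 probe sets at an unadjusted p under 0.05). With 3 splits no share under 0.05 can be had. Each other split also puts 1 vehicle and 1 treated array in every pair. Any group difference then adds to its residual spread, so its low counts are no measure of chance.

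The rise of the cell cycle list, by a median of 0.805 log2 units, was weighed against 3 technical explanations. A shift that depends on level is argued against by 10000 random lists of the same levels, whose highest median was 0.156 (permutation p = 1e-04, the smallest these draws can give). The draws took unrelated genes, while the list members had an estimated correlation of 0.667. This p therefore does not measure the spread between arrays, and the vehicle arrays had list means of 11.21 and 11.51. Quantile normalization again left the median at 0.807. It cannot decide about scaling between arrays, since the deposited values were already normalized and had upper quartiles of 10.09 to 10.12. A smaller share of some other cell type would raise the markers of all the remaining types. The highest median among 10 cell type lists, however, was 0.302 (differentiating spermatogonia, 10 genes). In 8 of the 8 lists with at least 5 tested genes the upper quartile lay below 0.805. These values do not bear on a larger share of a single cell type, which was not tested. The inhibitor may raise transcripts of dividing cells, a hypothesis found and tested on the same data, and an unrecorded difference in how the groups were cultured also stays open.

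Some genes of a neutrophil list were lower in the treated samples, and were looked at after S100a8, S100a9 and the stefins had been seen. Quantile normalization again cannot decide about scaling here either, and it left the S100a8 difference at -6.05 log2 units. Fewer blood cells in the treated pieces may account for it: on a marker list written after those genes were seen, all 7 markers above background on both vehicle arrays were lower on both treated arrays, but 4 of the 7 had been seen first, which leaves 3 (Mmp9, Il1b and Lcn2). Of the globins of red blood cells, 2 probe sets shared by alpha-globin genes fell by 3.12 and 2.95 log2 units (limma, adjusted p = 0.0087 and 0.0099), one shared by beta-globin genes differed by -2.45 and Hbb-b2 by -1.42 (adjusted p = 0.0637 and 0.0618; the former was -1.65 without treated array 1 and -3.24 without treated array 2), while Hba-a2 was at 13.05 with vehicle and 12.96 with WIN 18,446. Camp, Ngp, Ltf, Mpo, Elane, Csf3r and Itgam lay at the floor on nearly all arrays (2.28 at most, for Camp). Cxcr2, Cybb, Cd177, Itgb2, Prtn3, Ncf1 and Mmp8 lay there on all arrays, while S100a8 read 12.35 with vehicle. Macrophage genes were not called. Blood content and a change of the lower neutrophil genes in resident cells cannot be told apart. Few neutrophil markers lay above background, and the globin probe sets differ among themselves.

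In 17 of the 78 probe sets called at 4-fold or more that have a second tested probe set of their gene, that second one moved by under 0.25 of the shift or the other way. One probe set of Rps9, a ribosomal protein, went from 15.10 to 10.69, while another stayed at 15.24 and 15.06. A probe set of Eme2 likewise fell from 9.94 to 3.36, and another differed by -0.52. Those of Strn and Lbh rose by 5.05 and 5.86 log2 units, while another of each gene differed by -0.02 and -0.73. For Kctd14, 2 probe sets fell (-4.53 and -3.93), and another stayed at 14.88 and 14.84. In 17 of the 17 both treated arrays lay at least 0.5 of the shift away from both vehicle arrays. The calls fixed this (191 of all 191 called at 4-fold or more did so). It is therefore no test of a fault of 1 array, and it does not bear on faults of both treated arrays. Of 55 probe sets 4-fold or more apart between the treated arrays, 42 had a second probe set that did not follow, against 3 of 10 between the vehicle arrays. By the same rule, called or not, it was 19 of 95 between the groups. Of all 567 called probe sets with a second tested one, 538 moved the same way as the second. A linked block of inherited sequence differences between the groups is argued against, as 2 of the 16 genes had another within 100 tested genes. Scattered sequence differences under the probes, faults of both treated arrays and a change of transcript form by the inhibitor, each of which could act on single probe sets, were not tested.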

How the results depend on the processing

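The filter asking for 2 arrays at 5 or above was chosen after seeing the data; the other settings were planned. Of the 1083 called probe sets, 1079 remained called after quantile normalization again and 1078 with equal array medians. The count of 1083 (475 higher, 608 lower) went to 3 (0 and 3) without the level filter, where limma found 5250 probe sets at an unadjusted p under 0.05, to 372 (127 and 245) without a variance trend and to 2216 (1002 and 1214) at an adjusted p under 0.10; under the remaining settings with all 4 arrays it was within 1.5 times. The prior degrees of freedom were 3.19 as reported, 1.8 without the filter, which also raised the probe sets tested to 45037, and 1.98 without the trend; the cause was not tested. Leaving out 1 array gave 0 to 1398 calls (0 to 480 higher, 0 to 918 lower), with 0 without either vehicle array, 664 (259 and 405) without treated array 1 and 1398 without treated array 2; fewer samples leave 1 residual degree of freedom. Of 77 named genes called, 77 lost the call without the filter, 77 without either vehicle array, 41 without a trend, 22 without treated array 1 and 17 without treated array 2. The replicate numbers are shared by the groups, but nothing in the labels pairs them and same-numbered deviations correlate at 0.014; with a replicate block limma called 1467 probe sets, 1038 of them shared with the 1083. Of 7 lists called, 0 were called with an estimated correlation, a test with only 2 residual degrees of freedom. The retinoic acid response list had an adjusted p of 0.586 there. With fry 1 was called, that same list, and fry also called the Sertoli list. The lists that changed direction were called on neither side, and the cause was not tested. They were the meiotic list (adjusted p 0.81 without the filter, 0.906 with a mean of at least 7, 0.788 with 2 arrays at 5, 0.456 with fry, and 0.834 to 0.937 with 1 array left out), undifferentiated spermatogonia (0.82 without the filter, and 0.384 to 0.926), differentiating spermatogonia (0.923 without the filter), germ cells (0.91 without a trend, 0.88 with the mean over probe sets, and 0.661 to 0.926), aldehyde dehydrogenases (0.774 with a mean of at least 7, 0.979 without a trend, and 0.663 to 0.914), interferon response (0.99 with equal medians, 0.942 with the replicate block, 0.734 with fry, and 0.629 to 0.755), ribosomal proteins (0.928 with fry, and 0.113 to 0.834) and macrophages (0.0695 to 0.945). Among genes not called, Krt18 went to 0.05148 log2 units after quantile normalization again and 0.0004555 with equal medians. With 1 array left out Krt18 ran from -0.15 to 0.13, C1qb from -0.65 to 0.26 and Hba-a2 from -0.18 to 0.001959. In the same fits Tyrobp ran from -1.22 to 0.004952, and Rps9, by its brightest probe set, from -0.38 to 0.01232. Signal over background limits the fold of genes that reach the floor, such as Stra8 and Mybphl.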

Other observations

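The marker lists in this part were written, and their tests chosen, after the values of some of their members had been seen, so their p-values are not independent evidence.

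Of 14 tested genes on a list for striated muscle, 9 fell, 1 rose and 4 were not called by limma. Besides Mybphl and Myoz2, the membrane protein Hhatl fell from 8.70 ± 0.13 to 4.25 ± 0.36 (n = 2), the slow troponin subunits Tnni1 and Tnnt1 fell by 2.77 and 2.02 on the log2 scale, the formin Fhod3 by 3.01 and the myosin kinase Mylk3 by 2.65, and Tnni3, at 14.22 with vehicle, fell by 0.99. Tnnc1, which encodes another troponin subunit, rose by 3.05. Camera tested 2 of the 4 lists of this part, with p-values adjusted as for 4, and gave an adjusted p of 3.06e-09, and adjusted p = 0.0827 with an estimated correlation, so the call was lost there. Acta1, Actc1, Ckm and Myl2, abundant in muscle fibres, were below background on all arrays.

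Of 17 tested genes on a list for tight junctions, 4 fell, 0 rose and 13 were not called. Cgn, the cytoplasmic junction protein cingulin, fell 5.05-fold from 12.30 ± 0.06 to 9.96 ± 0.28, with limma's adjusted p at 0.00852, and Pard6b fell by 0.61 on the log2 scale, alongside Cldn11 and Cldn23, the first of them also on the Sertoli list. Jam2 was 0.31 and Tjp1 0.06 log2 units higher, and neither was called. Camera gave an adjusted p of 1.96e-05, and adjusted p = 0.0827 with an estimated correlation; the list was written after the values of Cldn11 and Cldn23 had been seen.

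Some proteases of mast cells were higher in the treated samples, and were left untested by the planned filter. Tpsb2 was at background with vehicle (2.11 ± 0.05) and at 6.66 ± 0.13 with WIN 18,446, Tpsab1 went from 2.08 ± 0.01 to 5.72 ± 0.81 and Mcpt2 from 2.05 ± 0.0081 to 6.62 ± 1.36, with adjusted p-values in limma of 0.00459, 0.0197 and 0.0268 under a filter of 2 arrays at 5 or above, which they pass on the treated arrays alone; with no filter these were 0.069, 0.11 and 0.147, and none was called. Without treated array 1 the Mcpt2 difference, taken from the highest bacterial control probe set (2.22), was at least 5.36 log2 units, and without treated array 2 at least 3.44. Cpa3 (2.05 and 2.20), Cma1 (2.06 and 3.09) and Mcpt4 (2.07 and 2.30) stayed under 5 in both groups. The planned filter tested 3 genes of the mast cell list (Gata2, Hdc and Srgn) and 0 were called, too few for a test of the list. Fcer1a and Ms4a2, subunits of the mast cell receptor for immunoglobulin E, were at background on all arrays.

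Among tested genes ordered along the chromosomes, 61 pairs of neighbours were both called, against a median of 44 and a highest value of 69 in 10000 random draws (one-sided permutation p = 0.0092). Of these pairs 46 moved the same way, among them S100a8 with S100a9, Tnnt1 with Tnni3, and Sox8 with its neighbour Cacna1h. No random draw was made for the shared direction. The pairs also include Wt1 with its opposite-strand transcript Wt1os, and related genes such as Cst12 with Cst9.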
